A study of Homo sapiens with 16 samples.

How the data were processed

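RNA of 16 cultures of Caco-2, a human colon carcinoma line that forms an intestinal epithelium in culture, was sequenced from a villus-on-chip device with magnetic actuation. Per the labels' protocols, mRNA was captured on polyT, fragmented and turned into libraries amplified by PCR, and no step of the protocol marks the strand. The labels name 4 treatments with 4 replicates each: a static control, a physiological swing, a pathological swing and an induction of inflammatory bowel disease (IBD). The agent, dose and duration of the induction are not given in the sources used here. The series design calls the replicates biological, but no label says whether they came from separate cultures or chips on separate days, so p-values measure the spread between these samples. A batch number is given for 1 sample alone and could not be used.

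Per the submitters' processing notes, the tools were fastp 0.23.4, FastQC 0.12.1, STAR 2.7.11a, featureCounts 2.0.6 and DESeq2 1.42.0 with the build hg38, without the settings of any of them. The authors deposited 4 tables of raw counts, whole numbers per gene, and 4 tables of FPKM, which are counts scaled by gene length and library size. Each table held 61228 gene rows and 4 libraries, and 0 of the 32 value columns were left unused. The tables carry the codes NOS1, VOS1, VOS2 and IBD. The code IBD was taken as the IBD induction and NOS1 as the static control, the second by elimination. VOS1 and VOS2 are the swing tables, and no label ties either code to the physiological or the pathological swing. The series design names the induced group IBD-VOS, and no label says which swing, if any, its chips received. All comparisons were therefore made between tables under their codes, and no direction was drawn that needs the swing label.

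The ratio of the deposited counts to the deposited FPKM gives the gene length used in each table. These lengths were within 1% of each other for 99.96% of genes among NOS1, VOS2 and IBD. They lay within 1% of the span of the whole gene in GENCODE v29 for 83.6% of 15287 genes. In VOS1 the implied length was shorter by over 1% for 92.8% of genes, with a median of 16.5% of the other length, and lay within 1% of the gene span for 2.41%. The length of ACTB was 4405 bp in VOS1 and 37494 bp elsewhere. VOS1 was thus counted over shorter features than the other tables. Counts of VOS1 against another table differ in this respect as well as in treatment, and genes that overlap a neighbour are the most exposed to it. The strand setting of the counting is not given in the sources used here, so counts of overlapping genes are uncertain in every table.

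Counts were analysed with edgeR 4.0.16 in R 4.3.3. One quasi-likelihood model held all 16 libraries in 4 groups, with TMM scaling and the default filter on low counts by group, which left 17123 genes. No block was used for the replicate number. Each of the 6 comparisons was adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. Gene lists were tested with camera of limma 3.58.1 on log2 CPM, with a prior count of 2 and a preset correlation between genes of 0.01. Camera was repeated with an estimated correlation, and fry was run beside it. There were 31 lists, covering immediate early, mechanical, inflammatory, epithelial, metabolic and stress genes and markers of other cell types, and a list needed 5 tested members. EGR1 was also compared by a two-sided exact permutation test of mean CPM over the 70 arrangements of 8 libraries.

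The groups, the edgeR and list tests, the 31 lists and the rule for named genes were set before the data were examined. The exact permutation test of EGR1 was not part of that plan. The rule named EGR1, the 8 higher and 8 lower genes with the largest fold change among those past the threshold with a mean log2 CPM of at least 2 and ranges that do not overlap, and up to 4 members of each list past camera. Pseudogenes and clone names were left out. The rule held in full for 4 comparisons and gave the other 2 only EGR1 and fewer list members. It was used in full for all 6, a choice made after seeing the data, because the swing codes could not be tied to the labels. A gene named outside the rule is said to be so. Some genes that the rule names are not reported here. For VOS1 the largest changes were taken among 3320 protein-coding genes that overlap no other gene in GENCODE v29 and have the same span in the tables, and those higher in VOS1 had to reach 1 CPM in the other table. This was also added after seeing the data.

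Alternatives were size factors of the RLE kind, library size alone, no filter, a minimum of 1 CPM in 4 libraries, a fold limit of 2, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a model of the groups compared alone, the replicate number as a block, and each replicate left out in turn. Other alternatives were added after seeing the data: 12 libraries without VOS1, the same 12 with the level of a group of 40 genes as a covariate, non-overlapping genes alone, and leaving out NOS1 replicates 1 and 4 or IBD replicates 3 and 4. FPKM was not used for comparisons with VOS1 because of its other lengths.

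The pipeline was tested on simulated data with 200 changed genes among 17123, and with the other tested members of the hypoxia list raised 2-fold. For IBD against VOS2 it recovered 32.8%, 74.6% and 89.4% of genes changed by 1.5, 2 and 4 fold. For IBD against NOS1 these shares were 31.3%, 65.7% and 90.9%, and for VOS2 against NOS1 35.8%, 67.2% and 84.8%. Genes called without a simulated change made up 7.36%, 4.52% and 5.19% of calls in the same order. Each gene was drawn independently, with no genes that vary together between libraries, so these shares may not hold for the real data. No pair of replicates agreed within counting noise, with a chi-square per gene of 5.50 or more in every pair. A gene at 3 counts, the limit that a count of 0 allows, corresponds to between 0.107 and 0.199 CPM per library. Such limits cover counting error only, since PCR reads without molecular identifiers are not independent molecules.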

Results

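Gene expression was measured by mRNA sequencing in 16 libraries of Caco-2 cells on an intestinal villus-on-chip, 4 each from the static table NOS1, the swing tables VOS1 and VOS2 and the IBD induction table. Total counts per library ran from 17537880 to 20021726 in NOS1, 15078620 to 18865457 in VOS2, 16307998 to 20609117 in IBD and 21868713 to 28148186 in VOS1. Mitochondrial genes took 3.92% to 6.94% of the counts. Among NOS1, VOS2 and IBD the Spearman correlation between libraries over 17123 genes was 0.976 to 0.995, and between VOS1 and any other table it was 0.786 to 0.821. The first principal component of all 16 libraries, which set VOS1 apart, held 89.8% of the variance. Without VOS1 the first component held 28.1%, and NOS1 replicates 1 and 4 lay at 56.2 and 42.0 on it, the other 10 libraries between -35.2 and 7.3. VOS1 was counted over shorter gene features than the other tables. The comparisons among NOS1, VOS2 and IBD share one way of counting and come first.

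The series title names EGR1, an immediate early transcription factor induced by growth factors and mechanical stimuli. It lies on chromosome 5 from 138465490 to 138469315 on the plus strand in GENCODE v29 (GRCh38, ENSG00000120738.7) and overlaps no other gene there. EGR1 was highest in VOS2, at 364 ± 14.1 CPM (SD, n = 4), followed by NOS1 at 234 ± 25.8 CPM. It was lowest in IBD, at 70.2 ± 34.3 CPM, and in VOS1, at 64.9 ± 29.9 CPM. EGR1 was 5.19-fold lower in IBD than in VOS2 (log2 fold change -2.38 ± 0.31 SE, edgeR quasi-likelihood adjusted p = 0.000247) and 3.33-fold lower than in NOS1 (-1.74 ± 0.30, adjusted p = 0.00445). The ranges of the libraries did not overlap in either comparison. EGR1 was at 37.2, 44.3, 96.7 and 102.8 CPM in IBD replicates 1 to 4, and without replicates 3 and 4 the log2 fold change was -3.17 against VOS2 and -2.53 against NOS1. In VOS1 it was lower than in VOS2 by a log2 fold change of -2.49 ± 0.31 and lower than in NOS1 by -1.85 ± 0.30. Between IBD and VOS1 the difference was within the spread of the libraries (0.11 ± 0.30, edgeR adjusted p = 0.76), and it was -0.67 without IBD replicates 3 and 4 (edgeR adjusted p = 0.0525).

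EGR1 in VOS2 exceeded that in NOS1 in every library, 349.5 to 380.2 against 195.4 to 248.8 CPM. The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 libraries allow (0.0343 after Benjamini-Hochberg adjustment over 6 comparisons). This test was not among those set before the data were examined. The exact test gave the same p in every comparison except IBD with VOS1 (0.857). Over all genes the rise of 0.64 ± 0.29 in log2 was not past the threshold (edgeR adjusted p = 0.664). It passed when no filter on low counts was used (adjusted p = 0.0334).

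**Figure D1:**
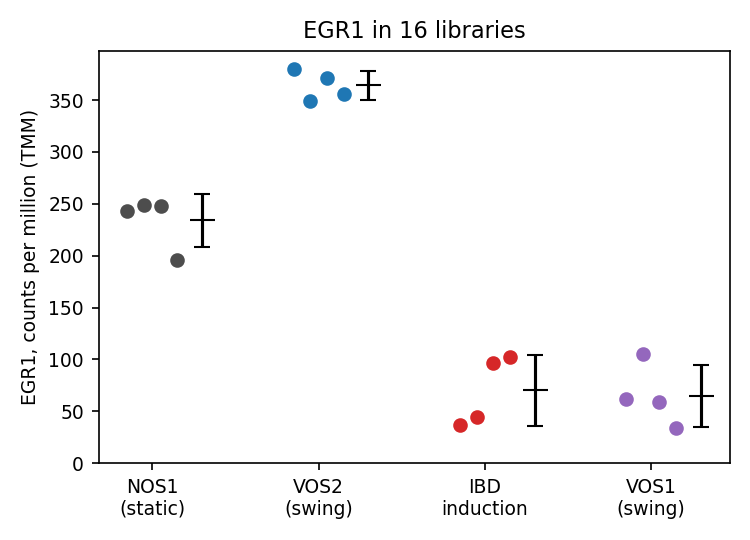
EGR1 in CPM after TMM scaling, 1 point per library, with the mean and SD of 4 libraries to the right of each table. VOS2 lies above NOS1, and the 4 IBD libraries lie between 37.2 and 102.8 CPM.

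Swing against static was compared between VOS2 and NOS1. No gene passed the threshold in edgeR among 17123, with 1220 at an unadjusted p below 0.05 and a smallest adjusted p of 0.286. DESeq2 called 14 genes (4 higher, 10 lower), limma on FPKM 0 with either pseudocount, and edgeR without a filter 468 (37 higher, 431 lower). Without NOS1 replicate 3 edgeR called 349 genes, 343 of them lower in VOS2. In camera 5 lists stood apart. The 13 mRNAs encoded by mitochondrial DNA were higher in VOS2 with a median log2 fold change of 0.28 (camera adjusted p = 5.3e-10), as were immediate early genes (median 0.20, adjusted p = 0.0039) and tight and adherens junction genes (0.10, adjusted p = 0.014). Adjusted over the list alone, 1 of 13, 1 of 26 and 0 of 37 members of these lists were higher. Relative to the mean of NOS1 and VOS2, the mitochondrial list lay at -0.38 in NOS1 replicate 4 and between -0.08 and -0.02 in the other NOS1 libraries, and the junction list at -0.14 and -0.11 in NOS1 replicates 1 and 4 and at 0.04 and 0.03 in replicates 2 and 3. Antigen presentation genes were lower (median -0.37, adjusted p = 0.0018), with 7 of 15 members lower when adjusted over the list alone, and so were interferon response genes (-0.14, adjusted p = 0.025, with 0 of 19 members past the test over the list alone). None of the 5 passed with an estimated correlation (adjusted p = 0.51 to 0.66), and no member passed over all genes. Outside the rule for named genes and chosen after its values were seen, PSMB8, an immunoproteasome subunit, averaged 12.7 ± 10.2 CPM in NOS1 and 2.93 ± 0.82 CPM in VOS2 (edgeR adjusted p = 0.286). The antigen presentation list lay at 0.49, 0.15, -0.19 and 0.35 in NOS1 replicates 1 to 4.

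NOS1 libraries differed among themselves more than VOS2 libraries. A group of 40 genes that were below 1 CPM in VOS1, among them the keratin KRT7, the intermediate filament VIM and the adhesion receptor CD44, stood in NOS1 at 100%, 16.7%, 6.14% and 60.3% of the level of replicate 1. In VOS2 the same genes lay between 5.70% and 15.4% and in IBD between 9.27% and 17.4%. KRT7 was at 246 CPM in NOS1 replicate 1 and 21.9 CPM in replicate 3. These genes were chosen from their values in VOS1 and in NOS1 replicates 1 and 3. The interferon, antigen presentation and junction lists did not pass between VOS2 and NOS1 without NOS1 replicates 1 and 4 (camera adjusted p = 0.37, 0.22 and 0.75) or with the level of the 40 genes as a covariate in the 12 libraries without VOS1 (0.23, 0.098 and 0.37). With 1 library left out the junction list was lost without NOS1 replicate 1 or 4 (0.10 and 0.058) and the interferon list without NOS1 replicate 1 or 4 or VOS2 replicate 1 or 2 (0.051 to 0.16).

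IBD was compared with VOS2, the swing table counted in the same way. The design names the induced group IBD-VOS but no label gives the swing of its chips, so induction and swing regime are not separated in the comparisons of IBD with VOS2 and with NOS1. Among genes past the threshold with a mean log2 CPM of at least 2 and ranges that did not overlap, the 8 with the largest rise were LCN2, SAA1, CCL2, MIR3142HG, PIGR, CEACAM7, CCL20 and BIRC3. LCN2, a siderophore-binding antimicrobial protein, averaged 44.5 ± 12.3 CPM in IBD and 1.04 ± 0.42 CPM in VOS2, a 42.7-fold rise (log2 fold change 5.42 ± 0.53 SE, edgeR adjusted p = 2.75e-05). The chemokine CCL2 rose 16.9-fold and CCL20 8.08-fold. PIGR, the receptor that carries polymeric immunoglobulin across the epithelium, rose 9.37-fold. BIRC3, an inhibitor of apoptosis induced by NF-kB, rose 7.53-fold, and CEACAM7 8.26-fold. In all 492 genes passed, 277 higher and 215 lower in IBD, of which 154 and 62 changed at least 2-fold. With library size alone as the scaling, 231 were higher and 250 lower. A fit of the 2 groups alone called 775 genes, DESeq2 783, edgeR without a filter 748, and limma 132 on log2(FPKM + 1) and 236 on log2(FPKM + 0.1). The count was 110 without IBD replicates 3 and 4. It was 230 without IBD replicate 4, 239 without VOS2 replicate 1, 242 without VOS2 replicate 4, 257 without VOS2 replicate 3 and 264 without IBD replicate 3.

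NF-kB targets and epithelial cytokines rose as a group, with 18 of 28 measured members higher, 0 lower and 10 not past the test (24 higher when adjusted over the list alone). The median log2 fold change was 1.48 (camera adjusted p = 6.8e-26, and 0.040 with an estimated correlation). CXCL5, a neutrophil-attracting chemokine, averaged 13.2 ± 2.15 CPM in IBD and 0.18 ± 0.21 CPM in VOS2. The cytokine LTB averaged 6.75 ± 0.98 and 0.14 ± 0.09 CPM. The 4 IBD libraries lay above all VOS2 libraries in 22 of 28 members, where the share by chance is 1.43% for a single gene. The members are not independent and the list had passed on the same values, so this is not a separate test. Mucosal defence genes rose in 9 of 20 members and fell in 1 (10 higher and 1 lower over the list alone), with a camera adjusted p of 1.3e-07 (0.035 with an estimated correlation). Besides LCN2 they included the acute-phase protein SAA1 (log2 fold change 4.39 ± 0.72) and the matrix protease MMP7 (14.6-fold). SAA1 has near-identical paralogs and overlaps another gene, so its counts are uncertain. The noncoding MIR3142HG, which rose 10.7-fold, overlaps another gene as well. In antigen presentation 3 of 15 members rose, among them TAPBP 1.61-fold and B2M 1.38-fold (5 over the list alone), and the list's camera adjusted p was 0.0010 (adjusted p = 0.29 with an estimated correlation).

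Cholesterol biosynthesis genes had a median log2 fold change of 0.33 over 24 members, of which 5 rose over all genes and 15 when adjusted over the list alone (camera adjusted p = 3.9e-10, and 0.035 with an estimated correlation). Relative to the mean of NOS1 and VOS2, the list lay at 0.22, 0.28, 0.44 and 0.51 in IBD replicates 1 to 4. FDPS, which makes farnesyl pyrophosphate, rose 1.61-fold and HSD17B7 1.44-fold. FDPS, FDFT1 and ACAT2 overlap other genes.

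Genes of the hypoxia response and glycolysis were higher in 17 of 35 members and lower in 0 (23 higher over the list alone). The median log2 fold change was 0.73 (camera adjusted p = 2.3e-16, adjusted p = 0.19 with an estimated correlation). NDRG1 averaged 911 ± 781 CPM in IBD and 148 ± 28.4 CPM in VOS2. In the 4 IBD libraries it was at 509, 120, 1915 and 1098 CPM. Relative to the mean of NOS1 and VOS2, the list's median was 0.35, -0.01, 1.31 and 0.90 in log2 in IBD replicates 1 to 4. CA9, ANKRD37 and PFKFB4 also passed, and each overlaps another gene. The brush border list lay at 0.18, -0.22, 0.58 and 0.35 in the same libraries. Brush border and enterocyte genes were higher in 4 of 39 members and lower in 1, the peptidase DPP4 (10 and 1 over the list alone), with a camera adjusted p of 0.0047 (adjusted p = 0.56 with an estimated correlation). The intestinal fatty acid carrier FABP1 rose 2.17-fold, from 374 ± 60.4 to 812 ± 206 CPM, and APOC3 3.49-fold. Without IBD replicates 3 and 4 the list lay on the other side of 0, with an adjusted p of 0.996. The goblet cell genes ZG16 (20.5 ± 17.9 against 2.14 ± 1.00 CPM) and TFF1 (42.7 ± 19.1 against 15.0 ± 4.31 CPM) rose among 18 measured members, 6 of which rose over the list alone (camera adjusted p = 0.026, adjusted p = 0.41 with an estimated correlation). The goblet list lay at 0.25, -0.36, 0.51 and 0.42 in IBD replicates 1 to 4 and between -0.12 and 0.15 in VOS2. Among 23 fatty acid oxidation genes and PPAR targets FABP1 and PPARG rose, with 6 higher and 1 lower over the list alone (camera adjusted p = 0.027, and 0.35 with an estimated correlation). That list lay at 0, -0.09, 0.21 and 0.20 in IBD replicates 1 to 4 and between -0.06 and 0.02 in VOS2. The goblet and fatty acid oxidation lists did not pass without IBD replicates 3 and 4 (camera adjusted p = 0.66 and 0.76), IBD replicate 3 (0.13 and 0.13), IBD replicate 4 (0.064 and 0.12) or VOS2 replicate 1 (0.068 and 0.054), nor the brush border list without IBD replicate 3 (0.18). In the 12 libraries without VOS1 the fatty acid oxidation list had an adjusted p of 0.079, and 0.14 with the 40 genes as a covariate.

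Under the same limits of level and range, the largest falls from VOS2 to IBD were those of EGR1 and of CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, which was 3.77-fold lower (106.6 ± 43.7 against 402 ± 43.8 CPM). Immediate early genes fell in 5 of 27 members and rose in 0 (12 lower over the list alone), with a median log2 fold change of -0.49 (camera adjusted p = 8.3e-06, adjusted p = 0.19 with an estimated correlation). The others past the test were CCN1 (2.90-fold lower), EGR4, IER2 and NR4A1, of which IER2 and NR4A1 overlap another gene. FOS, named after its values were seen, averaged 27.1 ± 18.6 CPM in IBD and 55.0 ± 6.21 CPM in VOS2 and did not pass (edgeR adjusted p = 0.159). Targets of the mechanically regulated cofactors YAP and TAZ fell in 7 of 22 members (10 over the list alone), with ANKRD1 3.01-fold and FJX1 1.74-fold lower (camera adjusted p = 8.5e-05, adjusted p = 0.19 with an estimated correlation). CCN1 belongs to both lists. Of the ERK feedback genes EGR1 and CCND1 were lower (2 of 15 members, 3 over the list alone, camera adjusted p = 0.011, adjusted p = 0.10 with an estimated correlation).

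The list of the unfolded protein and integrated stress response had 7 of 31 members lower and 0 higher, and 13 lower and 5 higher over the list alone (camera adjusted p = 0.00032, adjusted p = 0.19 with an estimated correlation). PPP1R15A, a phosphatase subunit that ends translational arrest, was 2.22-fold lower, the amino acid transporter subunit SLC3A2 1.64-fold and PHGDH, the first enzyme of serine synthesis, 1.56-fold. NRF2 targets and metallothioneins fell in 7 of 26 members and rose in 0 (10 lower over the list alone, camera adjusted p = 2.4e-06, adjusted p = 0.19 with an estimated correlation). AKR1C1 was 2.11-fold and GCLM, a subunit of the enzyme that starts glutathione synthesis, 1.57-fold lower. SLC7A11, the cystine transporter, is in both lists. AKR1C1 and AKR1C2 are close paralogs, as are the alkaline phosphatases ALPP and ALPG, which were 3.17-fold and 3.04-fold lower, and their counts are uncertain. Replication-dependent histone genes were lower and nuclear oxidative phosphorylation and ribosomal protein genes higher in camera, with no member past the test (adjusted p = 0.027, 2.4e-06 and 0.00039, and 0.26, 0.43 and 0.67 with an estimated correlation). The histone list did not pass without IBD replicate 1 (0.051) or 3 (0.062), nor the ribosomal list without IBD replicate 4 (0.069) or replicates 3 and 4 (0.19). The other 15 lists did not pass, with adjusted p from 0.091 for leukocyte markers to 0.93. Fibroblast markers had an adjusted p of 0.10 and endothelial markers 0.51.

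**Figure D2:**
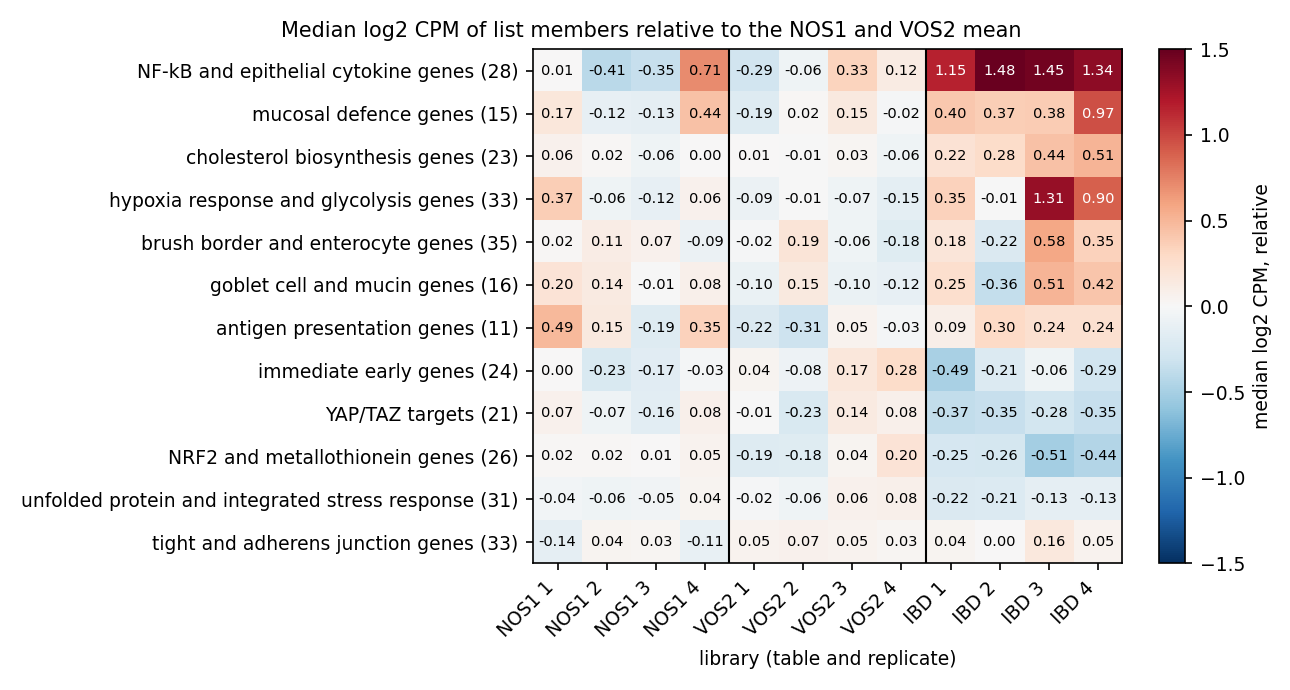
Median log2 CPM of the measured members of 12 lists in each of 12 libraries, relative to the mean of the NOS1 and VOS2 libraries, with the number of members in parentheses. NF-kB and cytokine genes lie between 1.15 and 1.48 in the 4 IBD libraries, while hypoxia and glycolysis genes run from -0.01 to 1.31.

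**Figure D3:**
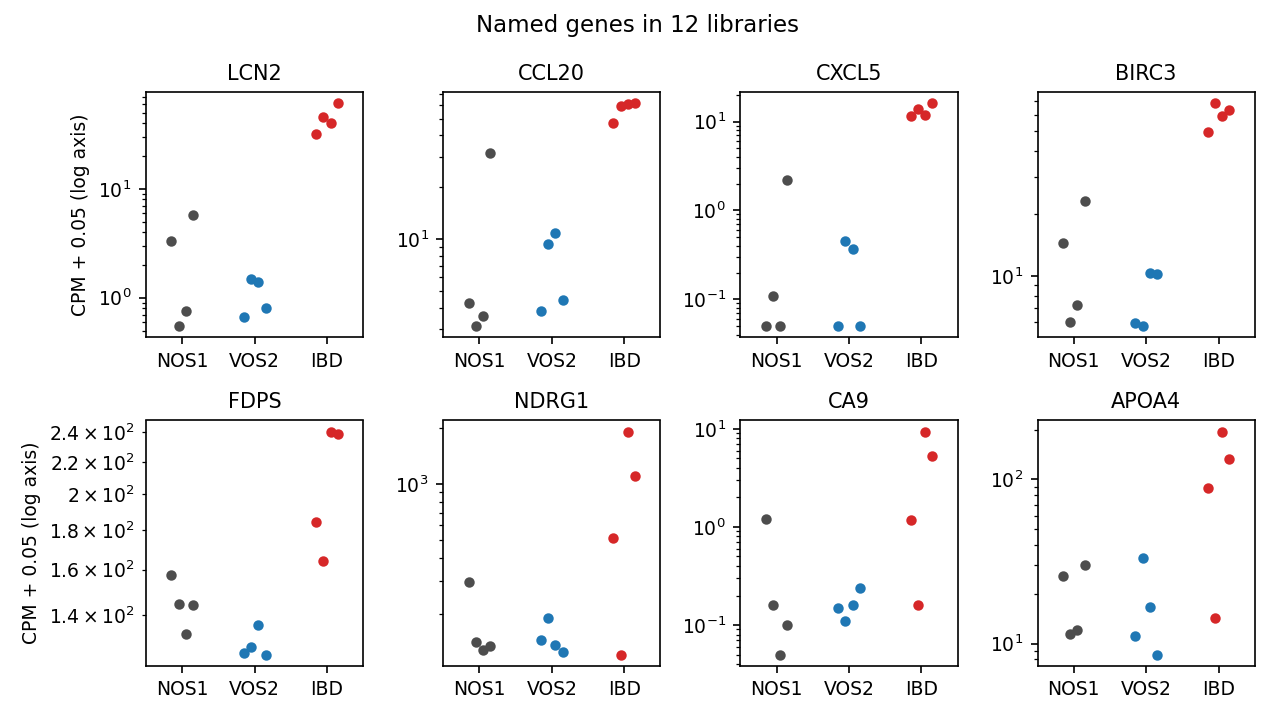
CPM plus 0.05 of 8 genes in the libraries of NOS1, VOS2 and IBD on log axes, 1 point per library. LCN2, CCL20, CXCL5, BIRC3 and FDPS are higher in each IBD library than in any VOS2 library, and NDRG1, CA9 and APOA4 in IBD replicate 2 lie below the highest VOS2 library.

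IBD was also compared with the static table NOS1. LCN2 was 17.2-fold higher (log2 fold change 4.11 ± 0.47 SE, edgeR adjusted p = 0.000108), CCL2 15.5-fold, PIGR 7.07-fold and CXCL8, which attracts neutrophils, 5.44-fold. In NOS1 replicate 4 CCL20 was at 31.7 CPM, against 3.08 to 4.20 CPM in the other NOS1 libraries. NF-kB and cytokine genes were higher in 16 of 28 members and lower in 0 (22 over the list alone, camera adjusted p = 3.7e-24, and 0.038 with an estimated correlation), with the list at 0.71 in NOS1 replicate 4 and -0.41 to 0.01 in the other NOS1 libraries. Mucosal defence genes were higher in 8 of 20 members and lower in 2 (11 and 2 over the list alone, adjusted p = 1.2e-06, and 0.038 with an estimated correlation). The mucosal defence list lay at 0.40, 0.37, 0.38 and 0.97 in IBD replicates 1 to 4, at 0.44 in NOS1 replicate 4 and between -0.13 and 0.17 in the other NOS1 libraries. Cholesterol biosynthesis genes were higher in 5 of 24 members, 13 over the list alone (adjusted p = 2.5e-09, and 0.038 with an estimated correlation), with SQLE 1.44-fold higher. In the leukocyte marker list LYZ (2.67-fold), AIF1 (3.61-fold, 1.67 CPM in IBD) and ITGAM (1.49-fold) were higher among 6 measured members (4 higher and 1 lower over the list alone, adjusted p = 0.0018, and 0.038 with an estimated correlation). LYZ encodes lysozyme, which intestinal epithelium also makes, and overlaps another gene.

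Hypoxia and glycolysis genes were higher than in NOS1 in 14 of 35 members, 22 over the list alone (camera adjusted p = 2.7e-11, adjusted p = 0.32 with an estimated correlation). The list lay at 0.37 in NOS1 replicate 1 and between -0.12 and 0.06 in the other NOS1 libraries, against 0.35, -0.01, 1.31 and 0.90 in IBD replicates 1 to 4. The mRNAs of mitochondrial DNA, at -0.38 in NOS1 replicate 4, were higher in 3 of 13, MT-ND4 by 1.41-fold (9 over the list alone, adjusted p = 1.9e-07, and 0.32 with an estimated correlation). Brush border genes had 6 of 39 members higher and 1 lower (11 and 2 over the list alone), with SLC5A1, the sodium-glucose transporter, 3.68-fold higher (camera adjusted p = 0.030, adjusted p = 0.79 with an estimated correlation). The list lay on the other side of 0 without IBD replicates 3 and 4 (adjusted p = 0.687). Junction genes (CGNL1 1.95-fold, F11R 1.28-fold), goblet genes (ZG16, TFF1) and nuclear oxidative phosphorylation genes were higher in camera, with 2, 2 and 0 members past the test (the same counts over the list alone), adjusted p of 0.030, 0.044 and 0.0022, and 0.58, 0.58 and 0.73 with an estimated correlation. The junction list lay at -0.14 and -0.11 in NOS1 replicates 1 and 4, at 0.04 and 0.03 in NOS1 replicates 2 and 3, and between 0 and 0.16 in IBD. The goblet list was at -0.36 in IBD replicate 2, against 0.25 to 0.51 in the other IBD libraries and -0.01 to 0.20 in NOS1. The nuclear oxidative phosphorylation list lay at -0.22 in NOS1 replicate 1, between 0.08 and 0.18 in the other NOS1 libraries and between 0.06 and 0.31 in IBD. Without NOS1 replicates 1 and 4 the brush border, junction, goblet and nuclear oxidative phosphorylation lists did not pass (camera adjusted p = 0.43, 0.63, 0.11 and 0.67), nor with the 40 genes as a covariate in the 12 libraries without VOS1 (0.38, 0.29, 0.053 and 0.073). The junction and goblet lists did not pass without IBD replicates 3 and 4 either (0.70 and 0.90). With 1 library left out, the brush border list was lost without NOS1 replicate 4 or IBD replicate 3 or 4 (0.059 to 0.53), the junction list without NOS1 replicate 1 or 4 or IBD replicate 3 (0.083 to 0.30), the goblet list without NOS1 replicate 3 or 4 or IBD replicate 3 or 4 (0.074 to 0.24) and the oxidative phosphorylation list without NOS1 replicate 1 (0.23).

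Lower in IBD than in NOS1 were CYP1A1 (4.07-fold), EGR1 and S100P (2.63-fold). NRF2 targets fell in 8 of 26 members, 10 over the list alone (camera adjusted p = 1.9e-07, adjusted p = 0.20 with an estimated correlation), among them the ferritin heavy chain FTH1 by 1.91-fold. FTH1, CGNL1, F11R and MT-ND4 overlap other genes. The stress response list fell in 7 of 31 members and rose in 1 (12 and 3 over the list alone, adjusted p = 0.015, and 0.40 with an estimated correlation). YAP and TAZ targets fell in 4 of 22 members (8 over the list alone, adjusted p = 5.5e-06, and 0.15 with an estimated correlation) and immediate early genes in 4 of 27 (4 over the list alone, adjusted p = 0.030, and 0.58 with an estimated correlation). In the cytoskeleton list VIM was 4.03-fold and FLNA 1.76-fold lower and ITGA2 1.49-fold higher, all 3 overlapping another gene (3 lower and 1 higher over the list alone, adjusted p = 0.027, and 0.58 with an estimated correlation). VIM is one of the 40 genes that were high in NOS1 replicates 1 and 4, where it was at 86.5 and 71.9 CPM, against 18.7 and 6.68 CPM in replicates 2 and 3. The immediate early and cytoskeleton lists did not pass without NOS1 replicates 1 and 4 (camera adjusted p = 0.23 and 0.44), with the 40 genes as a covariate in 12 libraries (0.11 and 0.16), without NOS1 replicate 1 (0.13 and 0.13) or without IBD replicate 1 (0.22 and 0.092), nor the stress response list without IBD replicate 1 (0.057).

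In total 647 genes differed between IBD and NOS1, 327 higher and 320 lower, of which 170 and 154 changed at least 2-fold. The split was 268 higher and 641 lower without NOS1 replicate 3, 236 and 404 without NOS1 replicate 2, and 270 and 359 with library size alone as the scaling. A fit of the 2 groups alone called 233 genes, DESeq2 981, edgeR without a filter 1249, and limma 89 on log2(FPKM + 1) and 198 on log2(FPKM + 0.1). Without NOS1 replicates 1 and 4 the count was 174, and without IBD replicates 3 and 4 it was 83. It was 229 without IBD replicate 4, 234 without IBD replicate 3, 240 without NOS1 replicate 4, 309 without NOS1 replicate 1 and 405 without IBD replicate 1.

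VOS1 differed from the other tables in most genes. Against NOS1 11018 genes passed (6155 higher, 4863 lower), against VOS2 11013 (6275 higher, 4738 lower), and IBD against VOS1 gave 10660 (4615 higher, 6045 lower). With library size alone as the scaling, the splits were 5024 and 6651, 5061 and 6633, and 6124 and 4938, and the median over all genes shifted by -0.21, -0.22 and 0.18 in log2. HNRNPA1, an abundant RNA-binding protein, averaged 2116 ± 164 CPM in VOS1 and had 0 counts in the 12 other libraries, as did RPS4X (1315 ± 56.5 CPM). Of 814 genes with at least 5 CPM in VOS1 and at most 3 counts in the 12 others, 725 had a position in GENCODE v29, and 695 of those (95.9%) overlapped another gene. Among the other 10023 genes this share was 67.0%. The treatment and the way of counting cannot be told apart in these totals.

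**Figure D4:**
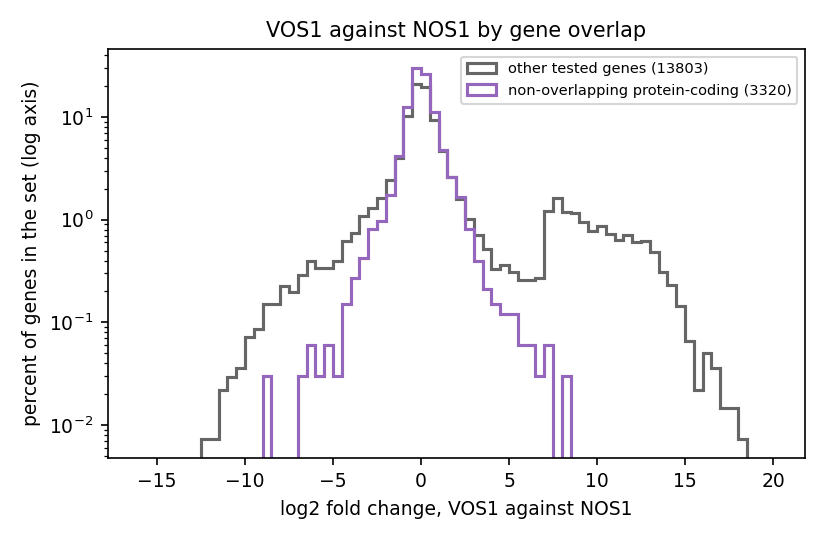
Distribution of the log2 fold change of VOS1 against NOS1, as a percent of the genes in each set on a log axis, for 3320 protein-coding genes that overlap no other gene and for the other tested genes. The other genes include a shoulder at high values in VOS1 that the non-overlapping genes lack.

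Among the 3320 genes that overlap no other gene, tested alone, 1868 differed between VOS1 and NOS1 (924 higher, 944 lower) and 1850 between VOS1 and VOS2 (950 higher, 900 lower). These were 56.3% and 55.7% of the genes, whose counted length can still be shorter in VOS1. Where the VOS1 length was at least 0.8 of the other, 53 of 160 genes (33.1%) differed from NOS1. Against VOS2 it was 66 of 160 (41.25%). The genes named below are not among these 160, so their changes may include the way of counting. Under the rule for named genes the largest rise among the 3320 was that of TPD52L2, 282-fold over NOS1, which was at 1.07 ± 0.46 CPM there and also near 1 CPM in VOS2 and IBD. This near absence from every other table resembles that of HNRNPA1 and RPS4X, so the rise of TPD52L2 cannot be told apart from the way of counting. Overlaps were taken from GENCODE v29, which may not be the annotation used in counting. NDRG1 averaged 3096 ± 718 CPM, against 174 ± 80.9 CPM in NOS1. The salivary cystatin CST1 was 93.9-fold and ZG16 32.6-fold higher than in NOS1. Lower in VOS1 than in both tables were the antiprotease SLPI (7.63-fold against NOS1), the DNA sensor IFI16 (6.96-fold) and DHRS2 (13.4-fold). Against VOS2 FOSL1, an immediate early transcription factor, was 5.01-fold lower. IBD exceeded VOS1 in LCN2 (15.8-fold), the macrophage growth factor CSF1 (4.51-fold) and the protease CTSS (4.41-fold).

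In the list test over all genes VOS1 was higher than NOS1 in hypoxia, cholesterol, junction and ribosomal protein genes and lower in proliferation genes, of which 24 of 40 were lower and 1, FOXM1, higher. The camera adjusted p was 0.00061 for hypoxia and for proliferation, 0.0015 for cholesterol, 0.026 for junction and 0.036 for ribosomal protein genes. Against VOS2 the same directions held except that junction genes did not pass (adjusted p = 0.00020, 0.0012, 0.0012 and 0.0091 for hypoxia, cholesterol, proliferation and ribosomal genes), and IBD was higher than VOS1 in proliferation genes (adjusted p = 0.0026). Of the 5 calls against NOS1, 3 were kept without NOS1 replicates 1 and 4, and with library size alone, without NOS1 replicate 1 or without VOS1 replicate 4 it was 4. Of the 4 against VOS2, 3 were kept with library size alone or without VOS1 replicate 4. None of these calls passed with an estimated correlation (adjusted p = 0.95, 0.83 and 0.93), and many members overlap other genes.

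**Figure D5:**
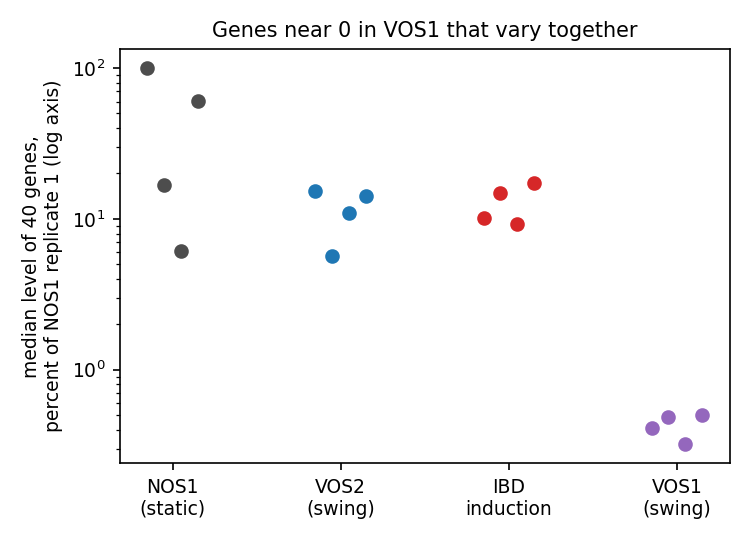
Median level of the 40 genes that are below 1 CPM in VOS1, as a percent of NOS1 replicate 1 on a log axis, 1 point per library. NOS1 spans 6.14% to 100%, VOS2 and IBD lie between 5.70% and 17.4%, and VOS1 lies at 0.50% or below.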

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

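The tests of explanations in this part were chosen after the results were seen. In 267 groups of 4 libraries 27 values stood apart from the other 3 by the Dixon test, where about 13 would by chance. The gap to the nearest library is given as a share of the range of the group.

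NOS1 replicate 4 carried 8 of them. It was high in the chemokines CCL2 (0.947), CCL20 (0.961), CXCL3 (0.936) and CXCL5 (0.974), in LTB (0.928), MIR3142HG (0.832) and SAA1 (0.858), and low in EGR1 (0.899, at 195.4 CPM against 243.5 to 248.8). NOS1 replicate 1 was high in CA9 (0.906), MS4A10 (0.939), NDRG1 (0.918) and PPFIA4 (0.921). In VOS2, replicate 1 was low in MMP7 (0.843), replicate 3 high in SAA1 (0.915), and replicate 2 high in APOC3 (0.833) and in the mitochondrial share of counts (0.918) and low in TPD52L2 (0.855). In VOS1, replicate 3 was high in IFI16 (0.870) and low in PTGES (0.889), and replicate 4 was high in FOSL1 (0.851) and TPD52L2 (0.919) and low in METTL7A (0.853). In IBD, replicate 1 was low in CCL20 (0.836), replicate 2 high in CCN1 (0.935), and replicate 4 high in ACAT2 (0.854) and MMP7 (0.869) and low in EGR4 (0.942).

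The first pattern is the distance of VOS1 from the other tables. Of its 725 genes with a position and at most 3 counts over the 12 other libraries, 95.9% overlap another gene, consistent with whole gene bodies being counted in the other tables and reads in overlaps dropped. Such counting should not lower a gene in VOS1 by 2-fold where at least 80% of the body is exon and nothing overlaps it. This assumes even read coverage and that the GENCODE v29 overlaps hold for the annotation used in counting. Of 160 such genes 6 were lower by 2-fold against both NOS1 and VOS2, EGR1, DUSP2, VGF, SP8, KCTD12 and KLHDC7B. Under these assumptions, feature length and overlap alone do not account for these 6 genes. Other settings of the counting are not known. A separate batch or culture of the VOS1 chips, or the swing regime itself, stays open, because the number of tables counted in the way of VOS1 is 1 and batch and treatment cannot be told apart for it.

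The second pattern is the group of 40 genes near 0 in VOS1, which varied together in the other libraries. In the 10 libraries not used to choose them, the median absolute deviation over the genes of the log2 ratio to NOS1 replicate 1 was 0.265 to 0.750. The counting error of this ratio was 0.0896 to 0.251, below the deviation in each library. A changing share of cells of another kind may move the genes together, although one shared regulator could do the same. Such a share alone would keep 1 ratio apart from counting error, so the genes also varied in other ways. NOS1 replicates 4 and 2, not used in the choice, differed by 3.61-fold, so the genes were not raised alike in all static libraries. This cannot exclude an effect of the static condition with other variation between chips on top. The highest levels, 100% and 60.3%, were both in NOS1, and VOS2 and IBD lay between 5.70% and 17.4%. Whether fibroblasts, endothelial cells or leukocytes were present could not be decided. Only 12 of their 40 fixed markers overlap no other gene and were under 1 CPM in NOS1 replicate 3 (3 fibroblast, 3 endothelial and 6 leukocyte). These stayed at or below 0.682 CPM in NOS1 replicates 1 and 4, where the 40 genes were chosen to reach at least 20 CPM in replicate 1. The limit of 1 CPM can drop markers that follow the 40 genes. It would drop VIM, at 6.68 CPM in replicate 3 and 86.5 and 71.9 CPM in replicates 1 and 4. COL1A1, the highest fibroblast marker, averaged 24.4 CPM in NOS1 and 23.1 CPM in VOS2, but these means do not show replicates 1 and 4. Of 5 tested endothelial markers, 2 were lower and 0 higher in VOS2 than in NOS1 over the list alone. Whether epithelial RNA is displaced is open: the correlation of the 40 genes with the junction list over 12 libraries was -0.836 (Pearson, permutation p = 0.00297, adjusted 0.00594) and -0.385 (Spearman, permutation p = 0.220), but -0.0823 without NOS1 replicates 1 and 4, on which it rests.

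The third pattern is the uneven rise of hypoxia and glycolysis genes in IBD. The list's median differed by 1.32 in log2 among the 4 IBD libraries, against 0.49 among NOS1 and 0.14 among VOS2 libraries, so the list was not raised alike in all IBD libraries. The pattern was chosen for this spread. The range therefore cannot exclude an effect of the induction alike in all of them with other variation between chips on top. For NF-kB and cytokine genes the range was 0.33 in IBD and 1.12 in NOS1. Oxygen supply or cell density that differed between chips is a candidate explanation, and 21 of 35 members differed at least 2-fold among IBD libraries (14 among NOS1 and 5 among VOS2). No label gives oxygen or density, so it cannot be told apart from an uneven induction. High levels were not confined to the IBD table. In VOS1 32 of 37 members were higher and 1 lower than in NOS1. NDRG1 was at 2382 to 4063 CPM there, although VOS1 was counted over shorter features. In NOS1 replicate 1 the list lay at 0.37 and NDRG1 at 295 CPM, against 127 to 141 CPM in the other NOS1 libraries.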

How the results depend on the processing

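Alternatives with 12 libraries, non-overlapping genes, pairs of replicates left out and the 40 genes as a covariate were chosen after seeing the data, as were the counts over other splits. EGR1 kept its side of the threshold in 48 of 48 fits with 1 replicate left out and under every other alternative run except the unfiltered fit of VOS2 against NOS1 (0.64, adjusted p = 0.0334). Its difference between IBD and VOS1, which did not pass, ran from -0.14 to 0.43 in log2 with 1 replicate left out and so changed sign, and was -0.67 without IBD replicates 3 and 4 (edgeR adjusted p = 0.0525). No gene past the threshold and named by the rule reversed in any alternative run. With each replicate left out, 989 of 1224 calls of named genes and 256 of 288 calls of lists among NOS1, VOS2 and IBD were kept. Named genes kept 42 of 106 calls in limma with 1 added to FPKM, 58 of 106 with 0.1 added, 44 of 122 without IBD replicates 3 and 4, 39 of 74 without NOS1 replicates 1 and 4, 119 of 152 with only the groups compared and 132 of 153 with the replicate number as a block.

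Genes changed in IBD against VOS2 numbered 492 and in IBD against NOS1 647. With a fold limit of 2 they were 216 and 324, without a filter 748 and 1249, with DESeq2 783 and 981, with limma on log2(FPKM + 1) 132 and 89 and with 0.1 added 236 and 198. With only the groups compared they were 775 and 233, among non-overlapping genes 142 and 190, without IBD replicates 3 and 4 110 and 83, and without 1 replicate 230 to 676 and 229 to 909. IBD against NOS1 gave 174 without NOS1 replicates 1 and 4. In the 12 libraries without VOS1, IBD against VOS2 gave 674 and IBD against NOS1 858. In those 12 with the 40 genes as a covariate, the counts were 1075 and 562. VOS2 against NOS1 gave 0 in edgeR, 14 in DESeq2, 468 without a filter and 0 to 349 without 1 replicate. The VOS1 totals against NOS1, VOS2 and IBD were 6091, 6035 and 5597 with a fold limit of 2 and 1868, 1850 and 1792 among non-overlapping genes. The fold limit lowers counts by construction, and for the other settings the cause was not tested.

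Replicate numbers did not pair the libraries: same-numbered libraries correlated between -0.21 and 0.16 in their deviations, and the best match had the same number in 16 of 48 cases. With the number as a block IBD against NOS1 gave 427 genes and kept 14 of its 15 lists past camera.

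Lists past camera in VOS2 against NOS1 numbered 5 as reported, 9 in the 12 libraries without VOS1 (with all 5), 9 in those 12 with the 40 genes as a covariate and 8 without NOS1 replicates 1 and 4 (each with 2 of the 5), 5 to 8 without 1 replicate, and 0 in fry. With an estimated correlation IBD against VOS2 gave 3 lists, IBD against NOS1 4 and the other comparisons 0. IBD against NOS1 gave 15, of which 9 passed without NOS1 replicates 1 and 4 and 9 with the covariate. Fry gave 12 for IBD against VOS2 (9 of the 16 past camera), 8 for IBD against NOS1 and 28, 29 and 28 for VOS1 against NOS1, VOS2 and IBD. IBD against VOS1 gave 2 with library size alone, 5 without IBD replicates 3 and 4 and 1 to 2 without 1 replicate. VOS1 against NOS1 kept 3 of 5 without NOS1 replicates 1 and 4 and 4 of 5 with library size alone or without NOS1 replicate 1 or VOS1 replicate 4. VOS1 against VOS2 kept 3 of 4 with library size alone or without VOS1 replicate 4. Without IBD replicates 3 and 4 the brush border list did not pass against VOS2 (camera adjusted p = 0.996) or NOS1 (0.687). It lay on the other side of 0 in both, which at these p-values is no difference, and the cause of the loss was not tested.

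The 8 libraries of each comparison allow 35 splits into 4 and 4. A count of changed genes as large as the real one came in 1 split, the real one, for IBD against VOS2 (492, highest other 77), IBD against NOS1 (647, highest other 85), VOS1 against NOS1 (11018, highest other 342), VOS1 against VOS2 (11013, highest other 0) and IBD against VOS1 (10660, highest other 1402). A share of 1 in 35 is the smallest that these splits allow. The other splits mix the tables, so a true difference lowers their counts. The splits cannot tell treatment from a batch that follows the tables, or in VOS1 from the way of counting. For VOS2 against NOS1 35 of 35 splits gave as many genes as the real 0. The highest, 195, set NOS1 replicates 1, 2 and 4 with VOS2 replicate 1 against the rest, which points to a structure of the samples other than their table. These were the 4 of the 8 libraries with the highest level of the 40 genes (100%, 16.7%, 60.3% and 15.4% of NOS1 replicate 1), and whether these genes account for the 195 was not tested. For the number of lists, chance is not excluded in any comparison: 23, 2, 3, 28, 31 and 33 of 35 splits gave as many lists in the order VOS2 against NOS1, IBD against VOS2, IBD against NOS1, VOS1 against NOS1, VOS1 against VOS2 and IBD against VOS1, with highest others of 19, 16, 16, 13, 15 and 12. Only the number of lists was counted in each split, so no single list was tested in this way. Genes at or below 0.199 CPM, 3 counts in the shallowest library, are at the limit of the depth.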

Other observations

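The chemokine CCL2 and the cytokine LTB, both raised in IBD, were also higher in VOS1 than in NOS1, and the genes in this part were chosen after their values were seen. As a whole the NF-kB and cytokine list had 12 of 29 members higher and 6 lower in VOS1 than in NOS1 (12 and 6 over the list alone) and did not pass (camera adjusted p = 0.53). CCL2, a monocyte-attracting chemokine, was at 20.8 to 85.3 CPM in the 4 VOS1 libraries and 19.4 to 34.2 CPM in IBD, against 0.99 to 3.41 CPM in NOS1 (VOS1 against NOS1, log2 fold change 4.69 ± 0.51 SE, edgeR adjusted p = 2.57e-07). LTB was at 6.07 to 20.14 CPM in VOS1 and 5.42 to 7.70 CPM in IBD (VOS1 against NOS1, 5.08 ± 0.56, adjusted p = 3.00e-07). LCN2 was at 2.12 to 3.43 CPM in VOS1 and 2.54 ± 2.45 CPM in NOS1 (0.13 ± 0.48, adjusted p = 0.826), and at 44.5 ± 12.3 CPM in IBD. CCL2, LTB and LCN2 overlap no other gene in GENCODE v29, but VOS1 was counted over shorter features.

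CYP1A1 averaged 140.0 ± 18.3 CPM in VOS1, against 434.6 ± 61.3 CPM in NOS1 and 106.6 ± 43.7 CPM in IBD. Among the leukocyte markers LYZ was higher in IBD than in VOS2 (24.2 ± 1.94 against 7.53 ± 0.50 CPM, log2 fold change 1.68, edgeR adjusted p = 2.77e-07), while CD14 was lower (2.65 ± 0.29 against 4.42 ± 0.49 CPM, -0.73, adjusted p = 0.0156). Proliferation genes had 0 of 40 members past the test in IBD against VOS2 and against NOS1.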
